A study of Mus musculus with 12 samples.

How the data were processed

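The data were read counts per gene from RNA sequencing of 12 mouse samples in 4 groups of 3. The colon groups were total colons of mice labelled WT and labelled S1PR4 KO, taken at day 84 of treatment with AOM (10 mg/kg) and DSS (0.5%). The CD8 groups were CD8+ T cells sorted by flow cytometry from PyMT mammary tumors of mice labelled WT and labelled S1PR4 KO, when 1 tumor had a diameter of 1.5 cm. Groups were taken from the sample titles and the genotype, tissue and cell type labels. RNA was isolated with a column kit, and the 2 materials went through different library preparations, per the labels' protocols, so each material was fitted on its own.

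The values are read counts per Ensembl gene, per the file headers, and the deposited tables held whole numbers with no normalisation. The authors' alignment and counting involved STAR, TopHat2, RSEM, HTSeq and DESeq2 with the builds mm10 and GRCm38, per the submitters' processing notes, which give neither versions nor the role of each tool. Filters, removal of duplicate reads and strand-specific counting were not stated, so reads of overlapping or antisense genes cannot be told apart. The deposited colon tables held 30263 genes each. The deposited CD8 tables held 357 genes each, a part of a transcriptome whose selection was not stated, and all 357 were used.

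Gene IDs were matched to GENCODE vM21 on GRCm38, which held 30212 of the colon IDs (99.8%) and 356 of the CD8 IDs (99.7%). Total counts per colon library ran from 7304082 to 8652561. Sums over the listed genes of the CD8 libraries ran from 17407 to 183504 and are not depths. The highest count per annotated exon base was between 0.919 and 0.973 in the colon libraries. For colon genes that averaged more than 0.3 counts per exon base, 1176 in all, folds were therefore read as possibly compressed. Intervals, folds and floors cover counting error and the spread between these samples only, since the reads carry no molecular identifiers. Counts of replicate pairs differed by at least 2.87 times the sampling variance (chi-square per degree of freedom), so no library repeated another.

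Genes were kept with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (robust quasi-likelihood F test) in R 4.3.3. P-values were adjusted by Benjamini-Hochberg over all tested genes of a material, with a threshold of 0.05. In colon, 17195 genes were tested, and 352 of the genes in the CD8 tables were tested with TMM computed over the listed genes. Fold changes are the fitted log2 ratio of labelled KO to labelled WT with its standard error (SE), and group values are TMM-scaled counts on a common library size (CPM) with their standard deviation (SD). For a gene at 0 in every library of a group, the fold was bounded with a floor of 3 counts in each of those libraries. A total of 52 gene lists, for cell types and functions, were fixed before the data were examined, and those with 5 or more tested genes were tested with limma 3.58.1 camera. Camera used a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a material. Calls shared by both materials were compared with a 2-sided Fisher's exact test.

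The named genes followed a rule also fixed before the data were examined. It takes S1pr4 in every library. It takes the 10 higher and 10 lower genes with the smallest p among those past the threshold, or 5 and 5 where none passed, leaving out unnamed gene models, pseudogenes and immunoglobulin or T cell receptor segments. It takes the 4 members of each list with the smallest p, Pik3ap1 and Lta4h, the other S1P receptors, and Cd8a, Cd8b1, Cd3e and Cd4. Genes outside it are said to be chosen after their values were seen, and 1 gene that the rule takes is not reported here.

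The gene test was tested on simulated data with the real means and library sizes. With spread as in the colon libraries and 200 genes changed among 17195, edgeR called 40% of genes changed 2-fold and 73.7% of those changed 4-fold, with 10 false calls. DESeq2 called 55% and 85% of the same genes with 53 false calls. With 40 genes changed among 352 as in the CD8 tables, edgeR called 50% of the 2-fold and 100% of the 4-fold changes with 1 false call. Camera called 0 of 50 colon lists and 0 of 1 CD8 list on the same data, in which no list was changed as a whole. Genes varied independently in these data, so the result does not cover lists whose members vary together between samples. The shares of changed genes called need not hold either where genes vary together. In a separate simulation, added after the results were seen, genes again varied independently and 10 lists of 49 tested were shifted by 0.25 (log2). Camera called 7 of the 10 and 1 other.

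Alternatives fixed before the data were examined were DESeq2 size factors, total counts as the only scaling, no filter on low counts, a mean of at least 50 counts, the replicate number as a block, each replicate left out in turn, DESeq2 1.42.0 and limma-voom with quality weights as tools. For the lists they were an estimated correlation and fry, and for the shared calls an unadjusted threshold. Chosen after seeing the data were a covariate for Xist or Y-linked reads, edgeR without robust estimation, and a restriction to colon genes of at most 0.3 counts per exon base, as was the CD8 fit with no scaling. An interaction of genotype and material was not fitted, because the CD8 tables hold part of the genes. S1pr4, Pik3ap1, Lta4h, Cd8a and Cd3e were not analysed in the CD8 libraries. Cd8b1 and S1pr5 did not pass the filter on low counts in colon.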

Results

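Gene expression was measured by RNA sequencing in C57BL/6 mice labelled wild type (WT) or labelled as lacking S1PR4 (KO), a receptor for sphingosine 1-phosphate found mainly on immune cells. There were 12 libraries in 4 groups of 3. Total colons came from day 84 of a model of colitis-associated tumors, in which azoxymethane (AOM, 10 mg/kg), a carcinogen, is combined with dextran sulfate sodium (DSS, 0.5%), which injures the colon lining. CD8+ T cells were sorted from mammary tumors of PyMT mice, which carry a viral oncogene in the mammary epithelium, when 1 tumor had reached 1.5 cm. The labels speak of triplicates and do not state whether each replicate was a separate animal, so every p-value measures only the spread between these samples.

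The colon libraries held 8652561, 7492925 and 8129264 counts in those labelled WT and 7919107, 7377424 and 7304082 in those labelled KO, over 30263 genes. The CD8 tables listed 357 genes. Counts over these genes summed to 57721, 183504 and 44811 in the libraries labelled WT and to 26702, 17721 and 17407 in those labelled KO. These sums are not depths, because the tables hold part of the genes and how they were chosen was not stated.

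The colon comparison asks how gene expression in the diseased colon differs when S1PR4 is lost. S1pr4 itself was counted in every colon library and was higher, not lower, in those labelled KO. Its raw counts were 61, 47 and 25 in the libraries labelled WT and 154, 162 and 118 in those labelled KO. S1pr4 (ENSMUSG00000044199, GRCm38 chromosome 10, 81497747 to 81500132, minus strand) averaged 5.54 ± 2.14 CPM (SD, n = 3) in WT and 19.1 ± 2.73 CPM (SD, n = 3) in KO, a log2 difference of 1.78 ± 0.34 (SE). It did not pass edgeR's quasi-likelihood test (adjusted p = 0.829) and passed DESeq2's test (adjusted p = 0.00442). Gene counts do not show which part of the gene the reads cover, so S1pr4 does not settle which animals lacked the receptor. WT and KO below name libraries by their labels, and every direction given rests on those labels.

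In colons labelled KO, genes of dividing cells and of intestinal stem cells were higher as groups, while genes of the muscle wall and its nerves were lower. All 23 proliferation genes measured had a higher mean in KO, with a median log2 difference of 0.24, as had 18 of 20 stem cell and WNT target genes, with a median of 0.56. All 14 smooth muscle genes and 14 of 15 enteric neuron and glia genes had a lower mean, with medians of -0.32 and -0.51. Camera called these 4 lists at its preset correlation and none of them with an estimated one (adjusted p = 0.861 with an estimated correlation for each). Within the 3 libraries with Y-linked reads, described below, KO replicate 1 was the only KO library. KO minus WT there stood at -0.09 for proliferation, 0.03 for stem cell, 0.21 for smooth muscle and 0.33 for neuron and glia genes. Among single genes, Hal, the enzyme that starts histidine breakdown, averaged 0.955 ± 0.291 CPM (SD, n = 3) in WT and 41.8 ± 37.0 CPM (SD, n = 3) in KO. Tdg, a DNA repair glycosylase, averaged 8.20 ± 0.538 CPM (SD, n = 3) in WT and 0.788 ± 0.391 CPM (SD, n = 3) in KO.

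No single colon gene passed the test. Of 17195 genes, 0 passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment (smallest adjusted p = 0.641), while 870 had an unadjusted p under 0.05, 451 higher and 419 lower, where chance gives 860. Limma-voom also called 0, with 4552 at an unadjusted p under 0.05, and DESeq2 called 14, with 6 higher and 8 lower in KO. On simulated data with this spread and 200 changed genes, edgeR called 40% of 2-fold and 73.7% of 4-fold changes. DESeq2 called 55% and 85% there with 53 false calls. Genes varied independently in those data, so these shares need not hold in the real libraries. The groups did not overlap for 1648 genes (9.58%), where chance gives 10%.

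Hal (ENSMUSG00000020017, chromosome 10, 93488768 to 93519304) had a log2 difference of 5.42 ± 0.78 (SE), and of 4.39 without KO replicate 1, which held 84.5 CPM against 20.6 and 20.2 in the other KO libraries. DESeq2 called Hal (adjusted p = 4.7e-12). Sfi1 and Stil, which act at centrioles, were also among the genes with the smallest p on the higher side. Their log2 differences were 0.39 ± 0.07 and 0.74 ± 0.15 (SE). On the lower side, Acta1, the skeletal muscle actin, differed by -1.48 ± 0.21, the RNA-editing enzyme Adar by -0.35 ± 0.06, and Tef, a transcription factor under circadian control, by -0.83 ± 0.16 (SE). DESeq2 called Acta1 (adjusted p = 1.1e-05) and Tef (adjusted p = 0.00452) and did not call Adar (adjusted p = 0.0797) or the 2 centriole genes (lowest adjusted p = 0.103). Each of these 5 genes had non-overlapping groups.

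Tdg (ENSMUSG00000034674, chromosome 10, 82629828 to 82650799) differed by -3.35 ± 0.37 (SE, log2). Its value is uncertain, because Gm9855, chosen after its values were seen, is a copy of Tdg with 99.2% identity over 1194 bases and differed the other way, by 2.82 ± 0.28 (SE, log2). The summed count of both genes differed by 0.16 ± 0.18 (SE, log2). DESeq2 called both genes, with adjusted p = 1.4e-06 for Tdg and 1.0e-06 for Gm9855. On chromosome 10, Tdg starts 1.13 Mb and Hal 11.99 Mb from S1pr4.

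**Figure D1:**
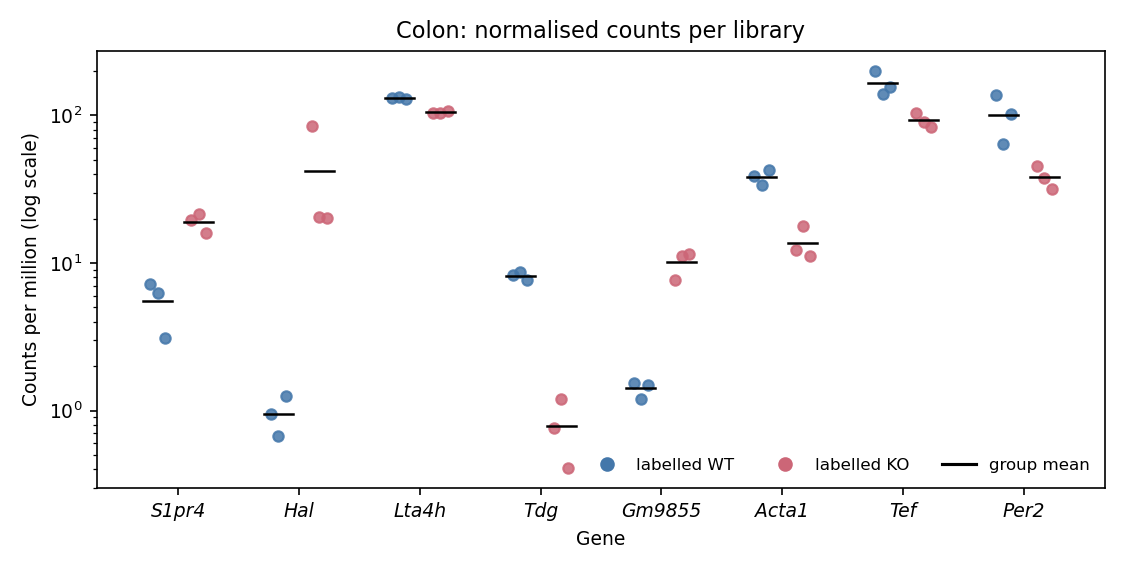
Normalised counts (CPM, log axis) of 8 genes in the 6 colon libraries, blue points for libraries labelled WT, red points for those labelled KO and black bars for the mean of each group. S1pr4 averages 5.54 CPM in WT and 19.1 CPM in KO, and Per2 and Gm9855 were chosen after their values were seen.

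**Figure D2:**
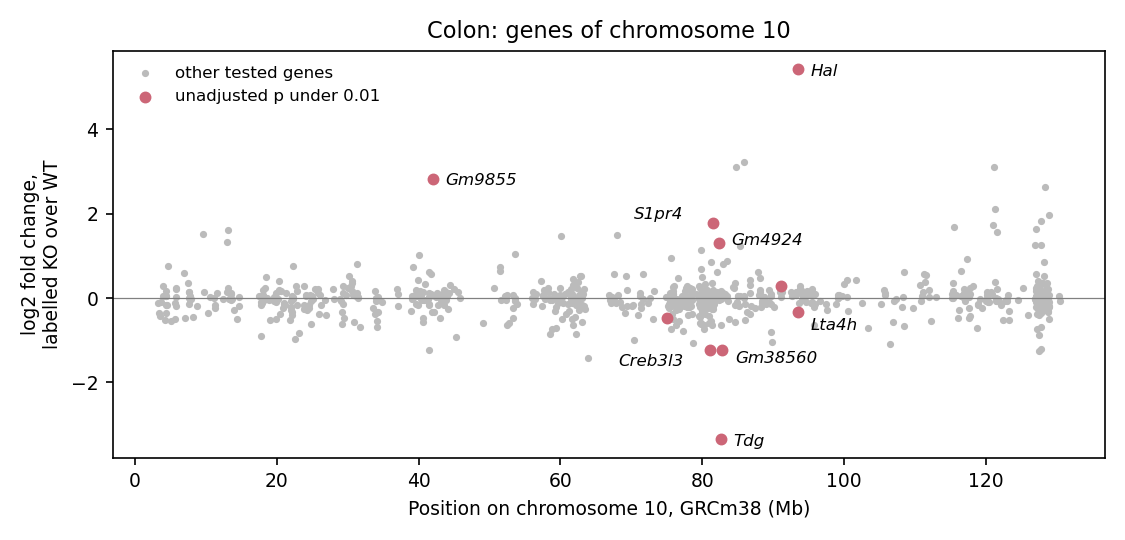
Fitted log2 difference of each tested colon gene on chromosome 10 against its start position in Mb (GRCm38), with genes at an unadjusted p under 0.01 in red. S1pr4 stands at 1.78, Tdg at -3.35 and Hal at 5.42, and Gm9855, a copy of Tdg, lies at 2.82.

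Of the 50 gene lists with enough tested genes, camera called 16, with 11 higher and 5 lower in KO. None of the 16 calls held when the inter-gene correlation was estimated (adjusted p = 0.861 with an estimated correlation for each of the 16 lists), and fry called 0, with a lowest adjusted p of 0.817. No member of any list passed edgeR's test over all genes, and 4 lists had a member that passed when adjusted over the list alone. The libraries also differed in Xist, which is expressed in female cells. Xist stood at 533 CPM in WT replicate 1 and at 606 and 517 CPM in KO replicates 2 and 3. It stood at no more than 6.64 CPM in the other 3 libraries, which held the Y-linked gene Ddx3y at 63.1 to 80.2 CPM. Differences within either set therefore rest on a single library, WT replicate 1 among the Xist-high and KO replicate 1 among the Y-linked ones. For 6 of the 16 called lists every Xist-high library lay on one side of every Y-linked library. With that status as a covariate, chosen after seeing the data, 11 of the 16 stayed called. The T cell activation, neutrophil, absorptive colonocyte, Paneth and ribosomal lists did not (camera adjusted p = 0.0869, 0.0772, 0.181, 0.276 and 0.0811). Of these, only the ribosomal list kept about the same median, 0.080 with the covariate against 0.087 without.

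Proliferation genes rose as a list (camera adjusted p = 7.9e-08, but adjusted p = 0.861 with an estimated correlation), and edgeR found none of its 23 members past the threshold. The members with the smallest p were Top2a, with a log2 difference of 0.36 ± 0.11 (SE), the nucleotide reductase subunit Rrm2 with 0.64 ± 0.24, Ccnb1 with 0.56 ± 0.22 and Bub1 with 0.55 ± 0.22. The mean of the list was higher in KO by 0.55 within the Xist-high libraries and stood at -0.09 within the Y-linked ones. Stem cell and WNT target genes also rose as a list (camera adjusted p = 1.4e-06, but adjusted p = 0.861 with an estimated correlation). Lgr5, a marker of crypt base stem cells, differed by 1.68 ± 0.60, Prox1 by 2.12 ± 0.84, Nkd1 by 1.24 ± 0.52 and Sp5 by 2.85 ± 1.24 (SE, log2). The list split the libraries by Xist, with a KO minus WT difference of 0.73 within the Xist-high libraries and 0.03 within the others, and its median was 0.26 without KO replicate 3. Cholesterol and sterol synthesis genes rose as a list as well, with 15 of 16 higher and a median of 0.25 (camera adjusted p = 1.8e-07, but adjusted p = 0.861 with an estimated correlation). Their members Fdps, Fdft1, Hmgcs1 and Lss differed by 0.85 ± 0.24, 0.37 ± 0.12, 0.29 ± 0.10 and 0.47 ± 0.17 (SE, log2). This list too split the libraries by Xist, with differences of 0.18 within the Xist-high and 0.23 within the Y-linked libraries.

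The colitis cytokine and chemokine list rose with 17 of 20 members higher and a median of 1.03 (camera adjusted p = 3.9e-04, but adjusted p = 0.861 with an estimated correlation). Il23a, which drives type 17 responses, differed by 2.63 ± 0.97, Il1a by 2.06 ± 0.77 and the neutrophil attractant Cxcl1 by 1.98 ± 1.04 (SE, log2). The neutrophil list rose with 9 of 11 members higher and a median of 1.41 (camera adjusted p = 0.00306, but adjusted p = 0.861 with an estimated correlation), among them Trem1 with 2.08 ± 1.02, Lcn2 with 1.71 ± 0.87 and Hdc with 1.41 ± 0.70 (SE, log2). Both lists split the libraries by Xist, with KO minus WT differences of 0.61 and 0.50 within the Xist-high libraries and 0.11 and 0.01 within the Y-linked ones. The Paneth and antimicrobial list rose with 14 of 15 higher and a median of 0.87 (camera adjusted p = 0.00319, but adjusted p = 0.861 with an estimated correlation), with Reg3g at 2.03 ± 1.25 and Nos2 at 1.18 ± 0.65 (SE, log2). It did not split the libraries by Xist, and differed by 1.04 within the Xist-high libraries and by -0.63 within the Y-linked ones. The neutrophil median was 0.87 without KO replicate 3 and 2.51 without WT replicate 1, and the call ended with a mean of at least 50 counts (camera adjusted p = 0.0514). The cytokine median was 1.77 without WT replicate 1 and 0.39 without KO replicate 2, where the call ended (camera adjusted p = 0.0764). The Paneth call ended without WT replicate 3, KO replicate 2 or KO replicate 3 (medians 0.51, 0.18 and 0.72, camera adjusted p = 0.0969, 0.179 and 0.0725).

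The smooth muscle list fell (camera adjusted p = 0.00110, but adjusted p = 0.861 with an estimated correlation), with the filament protein Synm at -0.70 ± 0.47 and the myosin kinase Mylk at -0.33 ± 0.24 (SE, log2). The enteric neuron and glia list fell (camera adjusted p = 8.8e-04, but adjusted p = 0.861 with an estimated correlation), with the neuronal genes Prph at -0.86 ± 0.51, Stmn2 at -0.64 ± 0.40 and Uchl1 at -0.62 ± 0.36 (SE, log2). KO minus WT was -0.90 and -1.26 for these lists within the Xist-high libraries and 0.21 and 0.33 within the Y-linked ones. The neuron and glia median was -1.24 without KO replicate 1, -0.33 without KO replicate 2 and -0.20 without KO replicate 3. The smooth muscle median was -0.53 without KO replicate 1, and that call ended without WT replicate 1 or KO replicate 3 (medians -0.14 and -0.09, camera adjusted p = 0.0569 and 0.259). The absorptive colonocyte list fell with 11 of 18 lower and a median of -0.12 (camera adjusted p = 0.0285, but adjusted p = 0.861 with an estimated correlation). Its members with the smallest p were Scnn1g, a subunit of the epithelial sodium channel, at -2.08 ± 0.55 and Ms4a10 at -1.01 ± 0.23 (SE, log2). This list split the libraries by Xist, with KO minus WT at -0.16 within either set, and its call ended without WT replicate 2, WT replicate 3 or KO replicate 3 (medians -0.047, -0.064 and -0.0055, camera adjusted p = 0.288, 0.107 and 0.428). Its median was -0.24 without WT replicate 1 and -0.23 without KO replicate 1. The xenobiotic and bile acid list fell with 15 of 19 lower and a median of -0.15 (camera adjusted p = 0.00498, but adjusted p = 0.861 with an estimated correlation). Ugt1a1, which conjugates bilirubin and shares exons with its family, stood at -1.004 ± 0.32 and the carboxylesterase Ces2a at -0.40 ± 0.17 (SE, log2), and the call ended without WT replicate 2, KO replicate 1 or KO replicate 3 (camera adjusted p = 0.0570, 0.0533 and 0.0823). The median of this list was -0.30 without KO replicate 2 and -0.065 without KO replicate 3, and KO minus WT was -0.35 within the Xist-high and -0.21 within the Y-linked libraries.

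**Figure D3:**
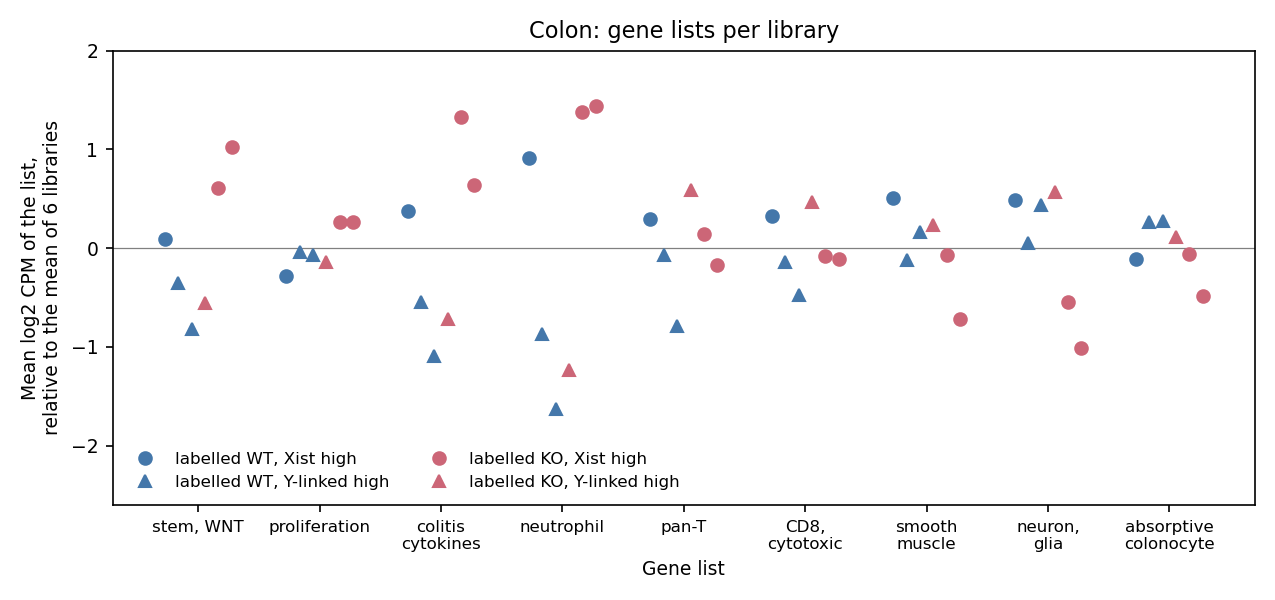
Mean log2 CPM of 9 gene lists in each colon library, relative to the mean of the 6 libraries, with blue for libraries labelled WT and red for those labelled KO. Circles are Xist-high libraries and triangles are Y-linked libraries, and the neutrophil list lies between 0.91 and 1.44 in the circles and between -1.63 and -0.87 in the triangles.

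The list of T cell receptor and pan-T genes rose with 16 of 18 members higher and a median of 0.29 (camera adjusted p = 0.00837, but adjusted p = 0.861 with an estimated correlation). Zap70, the kinase next to the T cell receptor, differed by 1.83 ± 0.71, and the receptor chains Trbc1 and Trbc2, near-identical genes whose reads can be shared, by 1.02 ± 0.42 and 0.82 ± 0.39 (SE, log2). KO minus WT for this list was -0.31 within the Xist-high libraries and 1.02 within the Y-linked ones, and the call ended without WT replicate 3 or KO replicate 1 (medians 0.08 and 0.02, camera adjusted p = 0.553 and 0.508). The median was 0.63 without WT replicate 1 and 0.51 without KO replicate 3. T cell activation genes rose with 13 of 15 higher and a median of 0.34 (camera adjusted p = 0.0285, but adjusted p = 0.861 with an estimated correlation). That call ended without WT replicate 3, KO replicate 1 or KO replicate 2 (medians 0.11, 0.23 and 0.22, camera adjusted p = 0.752, 0.0829 and 0.0764), and the median was 0.58 without WT replicate 1. KO minus WT was -0.12 within the Xist-high and 0.53 within the Y-linked libraries. The CD8 and cytotoxic list (camera adjusted p = 0.169) had 8 of 11 members higher and a median of 0.07. Its member Klrg1, a receptor of effector T cells and natural killer cells, averaged 0.915 ± 0.279 CPM (SD, n = 3) in WT and 2.60 ± 0.263 CPM (SD, n = 3) in KO, a log2 difference of 1.49 ± 0.31 (SE). Klrg1 was 1 gene past the threshold when adjusted over the list alone, with 0 over all genes in edgeR. Cd8a, Cd3e and Cd4 differed by -0.04 ± 0.57, -0.06 ± 0.55 and 0.08 ± 0.51 (SE, log2). These 3 differences lay within the spread between replicates and changed sign when single libraries were left out (Cd8a was 0.41 without WT replicate 1, 0.23 without KO replicate 2 and 0.22 without KO replicate 3).

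The remaining called lists were small shifts or rested on single libraries. Squamous and skeletal muscle genes fell with 9 of 9 lower and a median of -1.72 (camera adjusted p = 0.00319, but adjusted p = 0.861 with an estimated correlation). The list's mean in WT replicate 1 stood 3.09 above the mean of the 6 libraries, and without that library its median was 1.43, in the other direction (camera adjusted p = 0.569). KO minus WT was -2.81 within the Xist-high and -0.56 within the Y-linked libraries, which this list also split. Without KO replicate 1 that call also ended (camera adjusted p = 0.309). Krt10, a keratin of skin, stood at -2.32 ± 1.05 and Acta1 at -1.48 ± 0.21 (SE, log2), and Acta1 was the 1 member past the threshold when adjusted over the list alone. Krt10 was -0.08 without WT replicate 1. Adipocyte genes rose with 8 of 9 higher and a median of 0.98 (camera adjusted p = 0.00456, but adjusted p = 0.861 with an estimated correlation), including Cidec, Adipoq and Retn with 0.98 ± 0.34, 1.41 ± 0.71 and 1.54 ± 0.63 (SE, log2). The adipocyte call ended without WT replicate 2 (camera adjusted p = 0.0570) or KO replicate 1 (camera adjusted p = 0.531), with medians of 0.54 and 0.23, and the median was 1.52 without WT replicate 1. KO minus WT for this list was -0.21 within the Xist-high libraries and 1.77 within the Y-linked ones. Plasma cell genes rose with 15 of 17 higher and a median of 0.18 (camera adjusted p = 0.0349, but adjusted p = 0.861 with an estimated correlation). That call ended without WT replicate 1, WT replicate 3 or KO replicate 1 (medians 0.177, 0.155 and 0.047, camera adjusted p = 0.125, 0.0855 and 0.695). KO minus WT was -0.10 within the Xist-high and 0.57 within the Y-linked libraries. Ribosomal protein genes rose with 61 of 73 higher and a median of 0.09 (camera adjusted p = 0.0332, but adjusted p = 0.861 with an estimated correlation), and with 0.19 within the Xist-high and -0.06 within the Y-linked libraries. The ribosomal call ended without WT replicate 1, WT replicate 3 or KO replicate 2 (camera adjusted p = 0.287, 0.06003 and 0.810), with a median of -0.01 in the last case and of 0.15 without KO replicate 1 or KO replicate 3.

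Lta4h and Pik3ap1 are genes that the study followed up in CD8+ T cells after a choice made on these samples. Their values here are therefore not independent evidence. These values come from total colon, and neither gene was analysed in the CD8 libraries. Lta4h (ENSMUSG00000015889, chromosome 10, 93453411 to 93484875), the hydrolase that makes leukotriene B4, averaged 131 ± 1.52 CPM (SD, n = 3) in WT and 105 ± 2.67 CPM (SD, n = 3) in KO, a log2 difference of -0.32 ± 0.05 (SE). It missed the threshold over all genes in edgeR (adjusted p = 0.829) and was the 1 member of the leukotriene and arachidonate list past it when adjusted over the list alone. The list itself was not called (camera adjusted p = 0.480), with 8 members higher and 8 lower, and its other members with the smallest p were Alox5 at 0.97 ± 0.28, Alox15 at 1.99 ± 0.80 and Alox5ap at 0.56 ± 0.25 (SE, log2). Pik3ap1 (ENSMUSG00000025017), an adaptor of PI3 kinase, averaged 17.5 ± 10.2 CPM (SD, n = 3) in WT and 34.5 ± 14.1 CPM (SD, n = 3) in KO, a log2 difference of 0.97 ± 0.48 (SE) with overlapping groups (edgeR adjusted p = 0.829), which was 0.59 without KO replicate 3 and 1.57 without WT replicate 1. Pik3cg, a catalytic subunit of PI3 kinase in leukocytes, differed by 0.77 ± 0.20 (SE, log2) in a list that was not called (camera adjusted p = 0.743). The other S1P receptors S1pr1, S1pr2 and S1pr3 differed by -0.07 ± 0.30, 0.16 ± 0.22 and -0.52 ± 0.63 (SE, log2), and the S1P signalling list was not called (camera adjusted p = 0.834). S1pr2 lay between 0.05 (without WT replicate 2) and 0.42 (without WT replicate 1), and S1pr3 between -1.38 (without KO replicate 1) and -0.016 (without WT replicate 1). S1pr1 changed sign without WT replicate 1, KO replicate 2 or KO replicate 3 (0.25, 0.02 and 0.08).

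Other lists outside the threshold included type I interferon response genes (14 of 21 higher, camera adjusted p = 0.410), B cell genes (14 of 16 lower, camera adjusted p = 0.458) and T cell checkpoint genes (12 of 17 higher, camera adjusted p = 0.169). Macrophage and monocyte genes were higher in 15 of 18 cases (camera adjusted p = 0.169), and fibroblast genes lower in 14 of 20 (camera adjusted p = 0.271). Immunoglobulin variable segments, with 56 higher and 65 lower, were not called (camera adjusted p = 0.278), and 1 segment passed when adjusted over the list alone.

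The CD8 comparison asks how gene expression in T cells sorted from mammary tumors differs when S1PR4 is lost, and rests on the 357 listed genes. These include 0 of the 19 T cell receptor and pan-T genes. S1pr4 was not analysed here, so these labels were not checked. In the libraries labelled KO, Hal rose from 161 ± 49.2 to 3222 ± 1405 CPM of listed counts (SD, n = 3 each), a log2 difference of 4.41 ± 0.42 (SE). Treml2, a receptor of the TREM family, rose by 3.29 ± 0.62, and Enc1, an actin-binding protein, by 3.32 ± 0.62 (SE, log2). The secretoglobin Scgb2b27, from a multigene family whose reads can be shared, fell by 3.56 on the log2 scale (SE 0.57). The T-box factor Tbx15 fell by 1.89 (SE 0.39) and Nexmif by 3.21 (SE 0.67). The tetraspanin Tspan8 and the bicarbonate transporter Slc4a4 fell by 1.70 (SE 0.40) and 1.90 (SE 0.49). Raw counts in the KO libraries were 3, 0 and 8 for Scgb2b27, 7, 8 and 14 for Tbx15 and 3, 1 and 0 for Nexmif. They were 9, 3 and 3 for Tspan8 and 1, 4 and 5 for Slc4a4, so the size of these folds rests on few reads. The gene model Gm32687 (chromosome 10, 81863934 to 81881081), chosen after its values were seen, held 84, 174 and 107 counts in WT and 0 in each KO library, which makes it at least 8.45-fold lower against a floor of 3 counts per library.

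These 9 genes passed edgeR's quasi-likelihood test among 352 tested, with 3 higher and 6 lower and adjusted p-values from 1.0e-06 for Hal to 0.0366. An unadjusted p under 0.05 was found for 73 genes, and the groups did not overlap for 89 (25.3%), where chance gives 10%. That chance level holds only for genes listed without regard to the groups. How these genes were chosen was not stated, so neither count can be read against chance. The split depended on the scaling, with 1 higher and 4 lower by DESeq2 size factors, 4 and 20 by total counts and, chosen after seeing the data, 2 and 323 with no scaling, which moved the median of all genes from -0.01 to -2.57 (log2). Treml2, Enc1, Slc4a4 and Gm32687 were not called with DESeq2 size factors (edgeR adjusted p = 0.0554 each). The log2 differences of Treml2, Enc1 and Slc4a4 hardly moved there, at 3.26, 3.29 and -1.92. With no scaling Treml2 and Enc1 fell to 1.22 and 1.17 (log2) and were not called (edgeR adjusted p = 0.174 and 0.204). Hal stayed called, with raw counts of 12, 23 and 9 in WT and 42, 60 and 60 in KO, a ratio of means of 3.68. The size of these 3 rises therefore depended on the scaling. DESeq2 and limma-voom called 17 genes each. Hal and Scgb2b27 were called without any 1 of the 6 libraries, and each of the other called genes lost its call in at least 1 of these fits, among them Slc4a4, which stood at -1.20 (log2) without KO replicate 1. The number of calls was 4, 18 and 15 without WT replicates 1, 2 and 3, and 19, 2 and 3 without KO replicates 1, 2 and 3.

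Most listed genes had lower raw counts in KO and several were genes of mammary epithelium. The mean raw count was higher in KO for 6 genes and lower for 351, with a median KO to WT ratio of 0.168. The 6 genes, chosen after their values were seen, were Hal, Treml2, Enc1, the kinase subunit Camk2b and the histone genes Hist1h2ai and Hist1h2bl, whose near-identical copies can share reads. Camk2b averaged 28.7 ± 17.4 raw counts (SD, n = 3) in WT and 242 ± 33.9 raw counts (SD, n = 3) in KO. The 357 genes included 7 of the 16 mammary epithelial and milk genes and 4 of the 13 pan-epithelial genes. They included 0 of the 20 CD8 and cytotoxic genes. The pan-T, T cell checkpoint, naive, tissue-resident and T cell activation lists also had 0 members there. The CD4 and gamma delta T lists had 1 each. The epithelial adhesion gene Epcam held 778, 3187 and 1015 raw counts in WT and 513, 338 and 425 in KO. Relative to the listed genes Epcam differed by 0.56 ± 0.34 and Cldn4 by 0.45 ± 0.25 (SE, log2), which turned to -1.96 and -2.03 with no scaling. The milk protein genes Ltf and Lalba differed by -1.04 ± 0.35 and -1.25 ± 0.59 (SE, log2), and the mammary list was not called (camera adjusted p = 0.593). Lalba was -0.60 without WT replicate 3 and -1.58 without WT replicate 2. Ltf was 1 member past the threshold when adjusted over the list alone, with 0 over all genes in edgeR. The raw count ratio of Treml2 to Epcam, which needs no scaling, averaged 0.127 ± 0.0687 (SD) in WT and 0.8501 ± 0.171 (SD) in KO (2-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). Treml2 was named for its difference in these same libraries, and Epcam itself had lower raw counts in KO. The ratio is therefore not separate evidence that Treml2 rose.

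**Figure D4:**
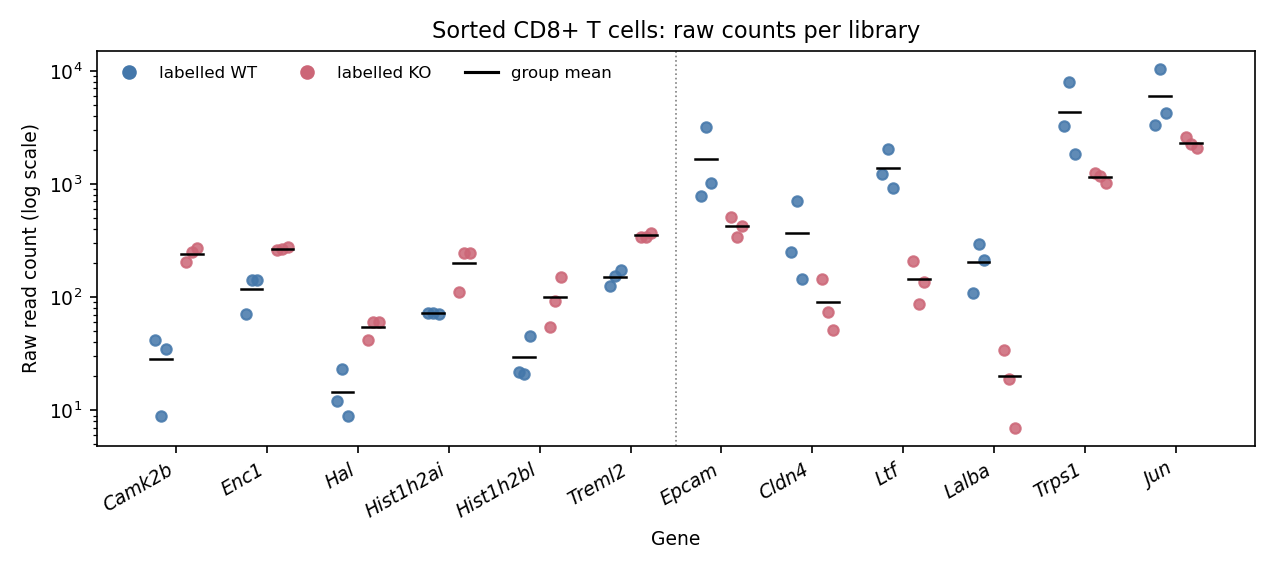
Raw read counts (log axis) of 12 listed genes in the 6 CD8 libraries, blue for libraries labelled WT, red for those labelled KO, with black bars for group means. The 6 genes to the left of the dotted line had a higher mean in KO, such as Treml2 with 151 counts in WT and 352 in KO, and the 6 to the right a lower mean, such as Epcam with 1660 and 425. Relative to the listed genes after TMM scaling, Epcam, Cldn4, Trps1 and Jun lay higher in KO instead.

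Whether the same genes moved in both materials was asked for the 325 genes tested in both. Colon had 0 calls among them and the CD8 libraries 6, so 0 were shared in edgeR. At an unadjusted p under 0.05, 18 colon and 65 CD8 genes passed and 4 passed in both (2-sided Fisher's exact p = 0.765). Of these 2 had the same direction, Hal and Camk2b, both higher in KO, where chance gives 0.738 higher and 0.923 lower. In colon Camk2b, chosen after its values were seen, differed by 1.11 ± 0.29 (SE, log2). The difference in effect between colon and CD8 cells was not tested.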

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

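The covariate for Xist or Y-linked reads, the fit without robust estimation, the restriction by exon length and the CD8 fit with no scaling were tests chosen only after the results were seen, and the others were planned. In colon, edgeR called 0 genes under each alternative that kept it as the tool, leave-one-out fits included, with 870 at an unadjusted p under 0.05 as reported, and limma-voom called 0. DESeq2 called 14 genes, 6 higher and 8 lower, among them S1pr4 (1.78, adjusted p = 0.00442), and the cause was not tested. S1pr4 lay between 1.51 and 2.03 in the leave-one-out fits, with adjusted p from 0.107 to 0.9999 in edgeR. The list count was 16, between 13 and 20 in the leave-one-out fits, 9 with a mean of at least 50 counts (fewer genes tested), and 0 with an estimated correlation and with fry. With that mean the pan-T and T cell activation calls ended (camera adjusted p = 0.233 and 0.372), as did the neutrophil, adipocyte, xenobiotic, plasma and ribosomal calls (camera adjusted p = 0.0514 each). The plasma and ribosomal calls also ended with total counts (camera adjusted p = 0.0507 and 0.0658), with no filter (camera adjusted p = 0.0551 and 0.139) and with the restriction by exon length (camera adjusted p = 0.176 and 0.0539). Leave-one-out medians reached from -2.27 to 1.43 for squamous genes and from -0.014 to 0.15 for ribosomal genes. Leaving out 1 library moved the log2 difference of 36 of 77 named colon genes and of 3 of 18 CD8 genes by over 1.5 times. Small differences changed sign, and the cause was not tested. Leave-one-out values reached from -0.79 to 0.41 for Cd8a, -0.61 to 0.51 for Cd3e, -0.71 to 0.43 for Cd4, -0.34 to 0.25 for S1pr1, -0.21 to 0.10 for Arntl, -0.14 to 0.015 for Clock and -0.34 to 0.0056 for Npas2. With limma-voom Cd4 was -0.37, with total counts Arntl was 0.0011, and with the covariate Arntl was 0.16 and Npas2 0.037.

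In the CD8 libraries the counts of 9 changed, 3 higher and 6 lower genes moved in most alternatives, and the cause was not tested except for fewer samples or genes. Leave-one-out fits called 2 to 19 genes, 1 to 11 of them higher and 1 to 12 lower. DESeq2 size factors gave 5 genes with 1 higher, total counts 24 with 20 lower and no scaling 325 with 323 lower. No filter gave 1 higher, and a mean of at least 50 counts 4 genes with 0 higher. Hal, Nexmif and Slc4a4 lay below that mean and were not tested there. DESeq2 called 17 with 9 higher, and limma-voom 17 with 10 higher. With no scaling Epcam was -1.96, Cldn4 -2.03, Trps1 -1.92, Jun -1.38, Treml2 1.22 and Enc1 1.17. Genes shared by both materials numbered 2 at an unadjusted p. With the replicate number as a block colon Cd4 was -0.15, and camera no longer called the absorptive colonocyte list (adjusted p = 0.0989) or the squamous list (adjusted p = 0.114). The squamous median was then 0.06, while camera still gave the list as lower. The CD8 fit with this block called 5 genes higher, among them Camk2b and Hist1h2bl (edgeR adjusted p = 0.0494 and 0.0350), and no longer called Slc4a4 (edgeR adjusted p = 0.159). The cause was not tested. Correlations between samples of the same number were -0.04, 0.21 and -0.23 in colon and -0.02, -0.10 and 0.22 in the CD8 libraries. They gave no clear sign that the numbers pair the samples, and 3 libraries per group are too few to exclude it. The CD8 fits of S1pr4, the interaction and the alternatives for normalised values were not run.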

Other observations

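All tests of an explanation below were chosen only after the result was seen, except the counts over other splits of the samples, which were planned. Several genes known to follow the circadian clock, chosen after their values were seen and in no list fixed in advance, had lower means in colons labelled KO, with edgeR calling none of them. Per2, a repressor of the clock, averaged 101 ± 36.4 CPM (SD, n = 3) in WT and 38.3 ± 6.82 CPM (SD, n = 3) in KO, a log2 difference of -1.40 ± 0.29 (SE). The clock-driven transcription factors Dbp and Hlf differed by -1.14 ± 0.25 and -1.53 ± 0.54, and Ciart and Per1 by -1.90 ± 0.49 and -0.88 ± 0.21 (SE, log2). DESeq2 called Per2 and Dbp (adjusted p = 0.00425 and 0.0399), while edgeR called neither (adjusted p = 0.829 for both). Nfil3, a repressor that opposes Dbp, was higher instead, by 0.76 ± 0.36 (SE, log2), and Arntl differed by -0.02 ± 0.21 (SE, log2), within the spread between replicates. A hypothesis is that the groups may have differed in time of day or clock state. Were it so in the usual opposite phase, the activators Arntl, Clock and Npas2 would be clearly higher, but their median log2 difference was -0.073, against -0.37 for Per3, Nr1d1, Nr1d2 and Cry1. Each activator differed by less than the spread between replicates, so the hypothesis stays open.

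The first pattern is that genes near S1pr4 on chromosome 10 differed between the labelled groups, with 5 colon genes within 15 Mb of it at an unadjusted p under 0.01 and a log2 difference above 1 in size, chosen after their values were seen, namely Hal, Tdg, Creb3l3 (-1.23 ± 0.32), Gm4924 (1.31 ± 0.31) and Gm38560 (-1.23 ± 0.29; SE, log2). Without Hal and Tdg, which prompted the test, the window held 3 such genes. So did 105 of the 10705 other windows of 309 genes (0.981%, none with more). Those windows overlap each other, so this share is not a p-value. In the CD8 libraries Hal and Gm32687 prompted the test, and 0 of the 4 other listed genes there were called, too few to decide. A candidate explanation is that sequence variants carried along with the targeted allele differ between the groups, which may also bear on Lta4h, 11.96 Mb from S1pr4 and next to Hal. For Tdg, reads shared with Gm9855 are a further candidate explanation, since the summed log2 difference was 0.16 ± 0.18 (SE), and 4 genes remain in the window without Tdg. No biological explanation was set apart by the design, since effects of losing S1PR4 on its neighbours would look alike, and the source of the S1pr4 reads in libraries labelled KO was not tested.

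The second pattern is the 16 gene lists called by camera in colon, for which members that vary together between samples beyond the preset correlation may account, since 0 calls were kept with an estimated correlation. For the cholesterol and sterol list, a covariate for sex, read from Xist and Y-linked counts, left a difference beyond the spread between libraries. Part of the shift went with the covariate, from 0.28 to 0.21 ± 0.015 (SE, log2) for the list's mean and from 0.25 to 0.16 for its median. In that fit WT replicate 1 is the only Xist-high WT library and KO replicate 1 the only Y-linked KO library. The list was also picked on these same data, so the fit does not exclude sex as the cause. For the other 15 lists sex cannot be told apart from other causes, because with the covariate 0 of them differed beyond the spread between libraries, as with proliferation at 0.23 ± 0.19 and neuron and glia at -0.47 ± 0.51 (SE, log2), although camera kept 11 of the 16 calls at the preset correlation. Medians shrank by over 1.5 times for 6 lists, such as neutrophil (1.41 to 0.51), Paneth (0.87 to 0.15), cytokine (1.03 to 0.50) and stem cell genes (0.56 to 0.27), and not for the other 10, such as proliferation (0.24 to 0.22), neuron and glia (-0.51 to -0.48), smooth muscle (-0.32 to -0.30), adipocyte (0.98 to 1.05) and squamous genes (-1.72 to -2.09). Less muscle wall in the pieces labelled KO cannot be told apart either. It would raise the neutrophil and absorptive lists alike, and their gap differed by 1.34 with an SE of 1.34. An effect of genotype stays open as well. The main axis of variation over the tested colon genes (principal component 1, 53.6% of the variance) set KO replicates 2 and 3 apart, at 40.9 and 69.6. The other libraries lay between -41.9 and -10.4, with the Xist-high WT replicate 1 at -21.3. This axis follows neither the Xist status nor the labels alone.

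The third pattern is the lower counts of most listed genes in the CD8 libraries labelled KO. Depth alone would not set genes apart from the rest, and 9 passed edgeR's test after scaling. That count was 5 with DESeq2 size factors and 2 without KO replicate 2. How the genes were chosen was not stated, so these counts do not exclude depth together with a choice by group. For the common factor, a median log2 difference of -2.57 with no scaling, depth cannot be told apart from lower expression, because whole-library depths were not used here. RNA of tumor epithelium that varies between sorted libraries, which the CD8 sort should remove, cannot be told apart either. A gap of 1.70 (log2) in the largest WT library, between the listed epithelial genes and the 6 genes higher in KO, decides nothing, because that library was ranked on the listed genes and the 6 genes were picked by their difference between the groups.

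Both materials have 10 splits of 6 samples into 3 and 3, the real one included, which are too few for a share under 0.05. For colon genes all 10 splits gave as many, with 0 for the real split in edgeR (870 at an unadjusted p under 0.05, 14 in DESeq2) and 17 for the highest other. That split separates the Xist-high from the Y-linked libraries, so Xist and Y-linked genes, which define it, are among its calls. Outside the X and Y chromosomes it called 10 genes, and whether these go with sex, another structure of the samples or false calls was not tested. For colon lists 9 of the 10 splits gave as many, with 16 for the real split and 31 for the highest other. The split by Xist and Y-linked genes gave 16 lists as well, and the other 8 splits 15 to 31. For CD8 genes 1 split gave as many, with 9 for the real split and 0 for the highest other. How the listed genes were chosen was not stated, and a choice by group would favour the real split. For CD8 lists 10 splits gave as many, with 0 for the real split and 1 for the highest other. Camera tested 1 list there, with an unadjusted p of 0.593.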
